A study of Mus musculus with 25 samples.

How the data were processed

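RNA from growing mouse satellite cell-derived myoblasts of 3 genotypes, wild type, MyoD-/- and p53-/-, was measured on 25 Affymetrix arrays. Satellite cells are the stem cells of adult skeletal muscle, and their cultured progeny are called myoblasts. Each genotype had 3 RNA samples, lettered A, B and C, which gave 9 samples in all. Every sample was hybridised to the chip types U74Av2 and U74Cv2, with 9 arrays each. U74Bv2 had 7 arrays, 3 of wild type, 3 of MyoD-/- and 1 of p53-/- (sample A). Per the labels, cells grew in Ham's medium with 20% fetal calf serum and 4 ng/ml bFGF on collagen-coated plates, were freed of other cells by preplating and serial passage, and were more than 98% pure by expression of desmin, Myf5 and MyoD. RNA was extracted with TriZol, per the labels. How the letters relate to mice or cultures is not given in the sources used here, so p-values measure the spread between these samples only. Signals of sex-linked genes differed between the letters of wild type and of p53-/-, so the letters of these genotypes were not all repeats of 1 RNA, while those of MyoD-/- were not told apart in this way.

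The deposited values were MAS5 signal intensities on a linear scale, 1 per probe set and array, and the authors made them with MAS5, per the labels. The MAS5 version and settings are not given in the sources used here. The 2% trimmed mean was 1500.8 to 1500.9 on the arrays of U74Av2, 1500.3 to 1500.4 on U74Bv2 and 1500.8 to 1501 on U74Cv2, so the arrays of a chip type were used as deposited, with no further scaling. The chips held 12488, 12477 and 11934 probe sets, of which 66 on each were control probe sets and were left out. The record file of each array gave its scan day and, for some arrays, its chip lot, which on U74Bv2 was recorded for wild type A alone. On U74Av2 all arrays but MyoD-/- A shared a scan day. On U74Cv2 the scan days fell the same way, and the chip lots separated wild type, MyoD-/- B and C with p53-/- A, and p53-/- B and C, while none was recorded for MyoD-/- A. On U74Bv2 wild type A, then wild type B and C with MyoD-/- A, then MyoD-/- B and C with p53-/- A made 3 scan days. Signals on these arrays carry no counts, so the number of arrays limits the precision, and with 3 arrays against 3 an exact permutation test of a single probe set cannot go below p = 0.1.

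The lists, tests, filters and alternatives described here were chosen before the data were examined, except where the text says otherwise. Signals were turned into log2(signal + offset), with the 20th percentile of all signals of a chip type as the offset, which came to 66.98 on U74Av2, 145.7 on U74Bv2 and 106.6 on U74Cv2. A probe set was tested if at least 3 arrays had it above the 40th percentile of that array, which left 7886, 7866 and 7883 probe sets. A linear model was fitted per chip type with limma 3.58.1 (eBayes with a trend, statmod 1.5.0, R 4.3.3), with genotype as the sole factor and all arrays of the chip type in the fit. The contrasts were MyoD-/- against wild type on all chip types, and p53-/- against wild type and MyoD-/- against p53-/- on U74Av2 and U74Cv2. P-values were two-sided and adjusted by Benjamini-Hochberg over all probe sets tested in a contrast, and an adjusted p under 0.05 was a call. The lone p53-/- array of U74Bv2 was compared with wild type apart from these counts, and its spread was assumed to be that of the other groups. Fold changes are on the log2(signal + offset) scale and understate the changes of dim genes. Errors of log2 fold changes are limma standard errors, and errors of mean signals are standard deviations over 3 arrays.

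Probe sets took their gene symbols from the annotation of the deposited platforms. Of the 36701 non-control probe sets, 29131 had a single symbol, 724 had several and 6846 had none, and 29044 of the single symbols matched the mouse gene table of assembly GRCm38.p6 by gene ID. That table served for names, for the chromosome of a gene and for the order of genes along chromosome 7. A gene was represented by its tested probe set with the highest mean percentile. Named genes were, for each contrast, the 12 with the largest positive and the 12 with the largest negative log2 fold change among called representative probe sets whose arrays did not overlap between the genotypes, up to 4 called members of each list with the smallest adjusted p, and a fixed set (Myod1, Trp53, Myf5, Myog, Pax7, Pax3, Des, Met, Cdh15, Cd34, Ly6a, Igf1, Cdkn1a, Mdm2, Ccng1, Bax, Bcl2 and Bcl2l1). Trp53, Pax7, Ly6a and Bax had no probe set with a single symbol and Pax3 did not pass the filter, so these 5 genes were not analysed here. Other genes named were chosen after their values were seen.

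The 22 gene lists, written from general knowledge of the genes, were myogenic regulators, muscle contraction and terminal differentiation, satellite cell markers, Notch pathway, p53 target genes, G1/S and DNA replication, G2/M and mitosis, cell cycle inhibitors, pro-apoptotic genes, anti-apoptotic genes, extracellular matrix, growth factors and receptors, interferon and antigen presentation, oxidative stress and xenobiotic defence, cholesterol biosynthesis, fibroblast markers, endothelial markers, macrophage and leukocyte markers, adipocyte markers, Schwann and neural markers, smooth muscle markers, and immediate-early and stress response. Each list was tested against all other genes with cameraPR at a preset correlation of 0.01 and, beside it, with camera at an estimated correlation. Beside these stood fry, which tests a list against no change and so answers another question. All were adjusted over the 22 lists. Counts of called members were also adjusted over the list alone. The overlap of the comparisons with wild type was set against the overlap of independent lists, and the covariance of their log2 fold changes against 100 simulations of unchanged groups on the same wild-type arrays.

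The fit was tested on simulated arrays with 200 changed probe sets. For MyoD-/- against wild type it called 33.3% of those changed by log2 1 and 83.2% of those changed by log2 2, with 5 of the unchanged probe sets called among 23355 tested. For p53-/- against wild type these shares were 43.4% and 80.6%, with 9 unchanged probe sets called among 15637 tested. The list test, run on 11951 simulated genes for MyoD-/- against wild type, called the 1 shifted list and 0 others. Simulated values were drawn independently for each probe set, so this run cannot show how often the list test errs where genes of a list are correlated.

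Alternatives changed the offset (none, double, a floor), the scaling (quantile normalization, median centring), the filter (none, a 60th percentile), the moderation, the groups in the fit, the level of adjustment, the probe set of a gene, the set test and the chips. A fit with the replicate letter, the scan day or the chip lot as a block and fits without each sample in turn were also made. On U74Av2 and U74Cv2 only MyoD-/- A had another scan day, so there the scan day block in effect left that array out. It adjusted nothing between p53-/- and wild type on these chip types. After the data had been seen, fits without the genes of chromosomes 4, 7 and 14, a fit of the lone p53-/- array with the scan day as a block and a list of imprinted genes were added. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.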

Results

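The series asked which genes change in growing myoblasts when MyoD, a transcription factor of the muscle lineage, or p53, a transcription factor that responds to DNA damage and other stress, is missing. Messenger RNA was measured on 25 arrays, with 9 arrays on U74Av2, 7 on U74Bv2 and 9 on U74Cv2. Wild type, MyoD-/- and p53-/- each had 3 samples, and p53-/- had a single array on U74Bv2. Median signals per array lay between 462 and 564 on U74Av2, 730 and 776 on U74Bv2, and 455 and 546 on U74Cv2. The ratio of 3' to 5' signal was 0.726 to 0.954 for Gapdh and 1.01 to 1.17 for actin. Sample p53-/- C had the highest Gapdh ratio and the lowest median signal on U74Av2 (0.887 and 462) and on U74Cv2 (0.954 and 455). Across probe sets, which are not independent replicates, Pearson's r between arrays was 0.9486 to 0.9742 within a genotype and 0.8489 to 0.9206 between genotypes on U74Av2. It was 0.9234 to 0.9508 within and 0.8149 to 0.8651 between genotypes on U74Bv2, and 0.9079 to 0.9336 within and 0.8642 to 0.9005 between genotypes on U74Cv2.

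Myod1, the gene targeted in the MyoD-/- mice, had its lowest signals in that genotype. Its signal on U74Av2 was 40930 ± 3930 (SD, n = 3) in wild type, 4843 ± 716 (SD, n = 3) in MyoD-/- and 22130 ± 3184 (SD, n = 3) in p53-/-. Myod1 fell by 3.07 ± 0.15 on the log2 scale in MyoD-/- (SE, n = 3, adjusted p = 3.09e-06) and by 0.89 ± 0.15 in p53-/- (SE, n = 3, adjusted p = 0.00445). Myf5, a transcription factor of the same family, was higher in both knockouts, at 726 ± 487 in wild type, 4331 ± 1469 in MyoD-/- and 5086 ± 898 in p53-/- (SD, n = 3). Myog, which drives the entry into terminal differentiation, stood at 5980 ± 1922 in wild type and 336 ± 88 in MyoD-/- (SD, n = 3), a log2 fold change of -3.87 ± 0.68 (SE, adjusted p = 0.00474). In p53-/- its log2 fold change of -2.11 was not called (adjusted p = 0.0762, range over 22 alternatives 0.0496 to 0.189), and it was called without p53-/- B (adjusted p = 0.0496). The direct contrast of Myog between the knockouts was not called (log2 -1.76, adjusted p = 0.124, range 0.000766 to 0.329), except without p53-/- C (adjusted p = 0.000766).

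Desmin, an intermediate filament protein of muscle, and Cdh15, a cadherin of myoblasts, fell in both knockouts. Des had a log2 fold change of -1.43 in p53-/- (adjusted p = 0.0221, range over 22 alternatives 0.00872 to 0.0746). That call was lost without wild type A (0.074), B (0.0588) or C (0.054), without p53-/- C (0.0746), with no offset (0.0559) and with a floor (0.0552). Cd34, a surface protein of quiescent satellite cells, rose in MyoD-/- (log2 3.28 ± 0.49, SE, n = 3, adjusted p = 0.00171). It was not called in p53-/- (log2 0.96, adjusted p = 0.256), and the direct contrast between the knockouts was log2 2.32 (adjusted p = 0.0108). Met, the receptor of hepatocyte growth factor, fell in MyoD-/- (log2 -1.41 ± 0.12, SE, adjusted p = 0.00015, on U74Bv2). It was not called in p53-/- (log2 0.08, adjusted p = 0.872, on another chip type). Its direct contrast was log2 -1.06 (adjusted p = 0.00964). Igf1 was not called in MyoD-/- (log2 -0.04, adjusted p = 0.898), in p53-/- (log2 -0.09, adjusted p = 0.741) or between them (log2 0.05, adjusted p = 0.869). The survival gene Bcl2 was not called at its representative probe set, with log2 fold changes of 0.53 in MyoD-/- (adjusted p = 0.127) and 0.21 in p53-/- (adjusted p = 0.565). Other probe sets of Bcl2 were called, at 1.94 (adjusted p = 0.00149) and 0.70 (adjusted p = 0.0471) in MyoD-/- and 1.26 in p53-/- (adjusted p = 0.0181). Bcl2l1, another survival gene, passed the threshold in MyoD-/- by little (log2 0.48, adjusted p = 0.0474, range over 22 alternatives 0.0322 to 0.156, under 0.05 in 10 of them). It was not called without wild type A (0.156), B (0.0658) or C (0.109), MyoD-/- A (0.0814), B (0.141) or C (0.0852), or p53-/- A (0.0695).

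**Figure D1:**
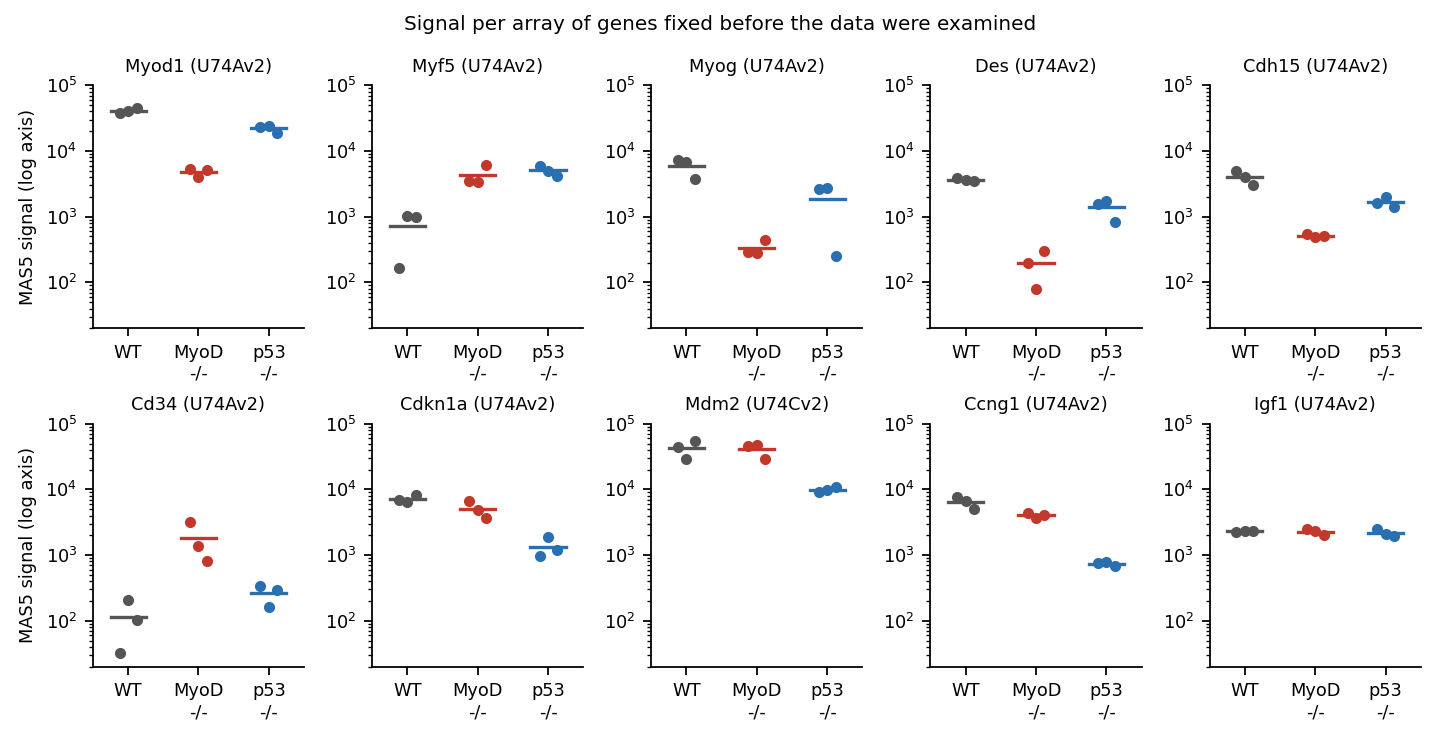
MAS5 signal on a log axis for genes fixed before the data were examined, with 1 point per array, 3 arrays per genotype, and a line at the mean. Myod1 averaged 40930 in wild type, 4843 in MyoD-/- and 22130 in p53-/-, and Cdkn1a averaged 7159 in wild type and 1349 in p53-/-.

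MyoD-/- against wild type asked what the loss of MyoD changes in growing myoblasts. Cells without MyoD had less RNA for the contractile apparatus, for the acetylcholine receptor through which nerves reach muscle, and for the fusion protein Mymk. They had more RNA for proteins of the extracellular matrix such as lysyl oxidase (Lox), which cross-links collagen, and biglycan (Bgn), a matrix proteoglycan. They also had more RNA for Ccn2, a matrix-bound growth factor, and Grem1, an antagonist of bone morphogenetic proteins. Of 16 cell cycle inhibitors 6 had less RNA, Cdkn2b among them. So had 6 of 49 p53 target genes, among them Gadd45a, which responds to DNA damage, and Pmaip1, which promotes apoptosis. Of the others 2 had more RNA and 41 were not called, and among all 12058 genes tested 823 had less and 742 had more. Of the lists behind these changes the matrix list alone kept its call with an estimated correlation between genes.

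Muscle contraction and terminal differentiation genes fell as a group. The list's median log2 fold change was -1.92, and 39 of 56 tested genes fell and 0 rose, or 44 and 0 adjusted over the list alone (adjusted p = 5.7e-38, and adjusted p = 0.138 with an estimated correlation). Acta1, the skeletal muscle actin, went from 19450 ± 7932 to 539 ± 247 (SD, n = 3), a log2 fold change of -5.00 ± 0.54 (SE, adjusted p = 0.000246). Chrna1, a subunit of the acetylcholine receptor, changed by log2 -5.08 ± 0.50 (SE, adjusted p = 0.000146), and the embryonic myosin Myh3 by -4.87 ± 0.47 (SE, adjusted p = 0.000134). The calcium release channel Ryr1 changed by log2 -4.13, the actin cross-linker Actn3 by -3.49 and the tropomyosin Tpm2 by -2.15. The troponin genes Tnnc1 and Tnnt3 changed by -4.55 and -4.52. Among the named genes outside the list, Lrrn1, a membrane protein with leucine-rich repeats, had the lowest log2 fold change at -6.39 ± 0.28 (SE, adjusted p = 1.72e-06). It was followed by Mest, a paternally expressed gene, at -6.36 ± 0.19 (SE, adjusted p = 7.59e-08), and by Car3, a carbonic anhydrase of muscle, and Peg3, a paternally expressed zinc finger gene, at -5.41 and -5.35. Mylk4, a myosin kinase, and Stac3, a protein of excitation and contraction coupling, changed by -5.35 and -4.90.

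Myogenic regulators and satellite cell markers fell on balance, with members in both directions. Of 28 tested regulators 3 rose and 9 fell, the same as adjusted over the list alone (median -0.20, adjusted p = 0.00436, and adjusted p = 0.157 with an estimated correlation). The regulators' call was lost without the genes of chromosomes 4, 7 and 14 (adjusted p = 0.136). Myod1, the targeted gene and itself a myogenic regulator on chromosome 7, fell by log2 3.07, which says nothing about the other regulators. Id3, an inhibitor of helix-loop-helix factors, fell by 1.77 on the log2 scale and the chromatin regulator Smyd1 by 2.73. Twist1, a mesenchymal transcription factor, rose by 2.93 ± 0.32 (SE, n = 3, adjusted p = 0.000252). Of 19 satellite cell markers 4 rose and 8 fell, or 4 and 10 adjusted over the list alone (median -0.61, adjusted p = 5.88e-06, and adjusted p = 0.138 with an estimated correlation). Cdh15 changed by log2 -2.80 ± 0.19 (SE, adjusted p = 1.97e-05) and Des by -3.94 ± 0.33 (SE, adjusted p = 6.57e-05), and the chemokine receptor Cxcr4 also fell (adjusted p = 6.43e-05). Of 24 Notch pathway genes 0 rose and 3 fell, or 2 and 3 adjusted over the list alone, and the list was not called (adjusted p = 0.185). Against no change, fry gave adjusted p = 0.0441 for it. The ligand Jag2 fell by 3.72 and Hes6, which promotes myogenic differentiation, by 1.79 on the log2 scale.

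Extracellular matrix genes rose as a group, with a median log2 fold change of 0.59. Of 53 tested genes 23 rose and 2 fell, or 28 and 2 adjusted over the list alone (adjusted p = 1.29e-13, and adjusted p = 0.035 with an estimated correlation, the 1 list that kept its call there). Lox rose by 5.54 ± 0.51 (SE, adjusted p = 0.000101), Fbln2, a matrix glycoprotein, by 5.02 ± 0.39 (SE, adjusted p = 4.22e-05), Col8a1 by 3.10 and the collagen hydroxylase subunit P4ha1 by 2.11 on the log2 scale. The laminin Lama2 fell by 2.77. Bgn went from 653 to 47970 ± 4865 (SD, n = 3). Col1a1 went from 994 ± 209 to 4950 ± 230 (SD, n = 3), and another of its probe sets went from 74.5 to 14750 ± 1930 (SD, n = 3, adjusted p = 5.36e-06). Fibroblast markers, of which 7 are also in the matrix list, rose in 5 of 13 tested genes and fell in 0, or 6 and 0 adjusted over the list alone (median 0.57, adjusted p = 0.00552, and adjusted p = 0.157 with an estimated correlation). Among them were Twist2 (log2 1.99, adjusted p = 0.00138) and gelsolin (Gsn, log2 1.91, adjusted p = 0.00768), while Col3a1, at 8602 ± 1612 in wild type and 7227 ± 987 in MyoD-/- (SD, n = 3), was not called (log2 -0.24, adjusted p = 0.559). S100a4, a calcium-binding protein, went from 23750 to 45360 (adjusted p = 0.0187, range over 22 alternatives 0.00524 to 0.0596). Its call was lost without MyoD-/- A (0.0526) and with the scan day as a block (0.0596), which on U74Av2 in effect leaves out that array. It was also lost without wild type B (0.0518) or MyoD-/- B (0.0576).

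Growth factors and receptors changed both ways. Of 51 tested genes 12 rose and 5 fell, or 16 and 8 adjusted over the list alone (median 0.19, adjusted p = 0.0339, and adjusted p = 0.631 with an estimated correlation). The list's call was lost without wild type B (0.11), MyoD-/- B (0.0866) or p53-/- B (0.0593). Against no change, fry gave adjusted p = 0.09. Ccn2 went from 340 ± 153 to 29820 ± 15560 (SD, n = 3), a log2 fold change of 6.09 ± 0.45 (SE, adjusted p = 3.08e-05). Bdnf, a neurotrophin, rose by 2.66 ± 0.20 (SE, adjusted p = 3.44e-05), and Igfbp3, which binds insulin-like growth factors, changed by -3.76 ± 0.32 (SE, adjusted p = 7.2e-05). Grem1 rose by 5.40 ± 0.73 (SE, adjusted p = 0.00183), Nrn1, a neuritin, by 5.68 ± 0.23 (SE, adjusted p = 5.5e-06) and Rasgrf1, an exchange factor for Ras, by 4.65 ± 0.28 (SE, adjusted p = 8.55e-06). Tfpi2, a protease inhibitor of the matrix, rose by 4.74, and Anxa8, an annexin, by 4.64. Serpinb9b, a serine protease inhibitor, rose by 6.69 ± 1.18 (SE, adjusted p = 0.00498), with 46570 ± 43590 (SD, n = 3) in MyoD-/- against 70.1 in wild type.

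The lists of p53 target genes and cell cycle inhibitors were called lower in MyoD-/- and that of anti-apoptotic genes higher, though most members of each were not called. Of 49 p53 target genes 2 rose and 6 fell, or 2 and 8 adjusted over the list alone (median -0.12, adjusted p = 0.0103, adjusted p = 0.8 with an estimated correlation, and adjusted p = 0.197 with fry). Pmaip1, a BH3-only protein, fell by 4.08 ± 0.18 (SE, adjusted p = 7.61e-06), Gadd45a by 3.32 ± 0.29 (SE, adjusted p = 8.04e-05) and Trp53inp1 by 2.06 on the log2 scale. Cdkn1a (log2 -0.54, adjusted p = 0.235) and Mdm2 (log2 -0.05, adjusted p = 0.943) were not called. Of 16 cell cycle inhibitors 0 rose and 6 fell, the same as adjusted over the list alone (median -0.49, adjusted p = 0.00068, and adjusted p = 0.337 with an estimated correlation). Cdkn2b stood at -2.76 ± 0.22 (SE, adjusted p = 4.57e-05). Of 23 anti-apoptotic genes 5 rose and 1 fell, or 10 and 1 adjusted over the list alone (median 0.46, adjusted p = 0.0147, and adjusted p = 0.157 with an estimated correlation). Tnfrsf11b, a decoy receptor, rose by 2.57 (adjusted p = 0.000363). Of 29 pro-apoptotic genes 3 rose and 5 fell and the list was not called (adjusted p = 0.257, the same counts adjusted over the list alone). The pro-apoptotic gene Bok rose by 1.26 and the kinase Dapk2 changed by -1.77. The lists of G1/S and DNA replication, with 0 of 51 genes up and 2 down, or 0 and 1 adjusted over the list alone (adjusted p = 0.523), and of G2/M and mitosis, with 2 of 50 up and 1 down in both counts (adjusted p = 0.203), were not called. G2/M and mitosis was called without MyoD-/- B (adjusted p = 0.000574).

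Of the other lists, cholesterol biosynthesis rose, with 3 of 19 genes up and 0 down, or 4 and 0 adjusted over the list alone (median 0.25, adjusted p = 0.0177, and adjusted p = 0.168 with an estimated correlation). The call was lost without wild type B (adjusted p = 0.0524). Ebp, a sterol isomerase, rose by 0.82 on the log2 scale (adjusted p = 0.00473). Oxidative stress and xenobiotic defence, with 7 of 36 genes up and 3 down, or 10 and 3 adjusted over the list alone, missed the threshold by little (adjusted p = 0.0504, under 0.05 in 11 of 26 alternatives). It was called without wild type C (0.0147), MyoD-/- C (0.00877), or p53-/- A (0.0485), B (0.00365) or C (0.0485). Its epoxide hydrolase Ephx1 rose by 3.93 ± 0.35 (SE, adjusted p = 9.33e-05). Interferon and antigen presentation had 3 of 30 genes up and 1 down in both counts and was not called (adjusted p = 0.111), except without wild type A (0.0471) or MyoD-/- C (0.0495). The lists of endothelial (0 of 5 genes changed, adjusted p = 0.924), macrophage and leukocyte (1 of 11 up, 1 down, adjusted p = 0.558), adipocyte (1 of 3 up, adjusted p = 0.312), Schwann and neural (2 of 10 up, 1 down, adjusted p = 0.737) and smooth muscle markers (0 of 13 up, 2 down, adjusted p = 0.959) were not called, and their counts were the same adjusted over the list alone. Immediate-early and stress response, with 2 of 27 genes up and 2 down, or 3 and 6 adjusted over the list alone, was not called (adjusted p = 0.523). Ier3, an early response gene, rose by 2.50 (adjusted p = 0.000634, not called at another probe set, log2 0.21, adjusted p = 0.802) while the transcription factor Fos fell by 1.40 (adjusted p = 0.00201). In the uncalled lists of pro-apoptotic, endothelial, macrophage, smooth muscle and immediate-early genes the median, mean and test did not share a sign.

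In all, 2515 of 23635 probe sets differed between MyoD-/- and wild type, or 10.6%, with 1178 higher and 1337 lower. Of these 639 were at least 2-fold higher and 742 at least 2-fold lower. Counted as genes, 1565 of 12058 changed, with 742 up and 823 down. The arrays of the genotypes did not overlap for 3798 of the 12058 genes, or 31.5%, where chance gives 10%. The count of probe sets was 1602 without wild type A, 1452 without wild type B and 1610 without MyoD-/- B, and 1847 with the scan day as a block. It was 1561 on U74Av2 and U74Cv2 alone, where fewer probe sets were tested.

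**Figure D2:**
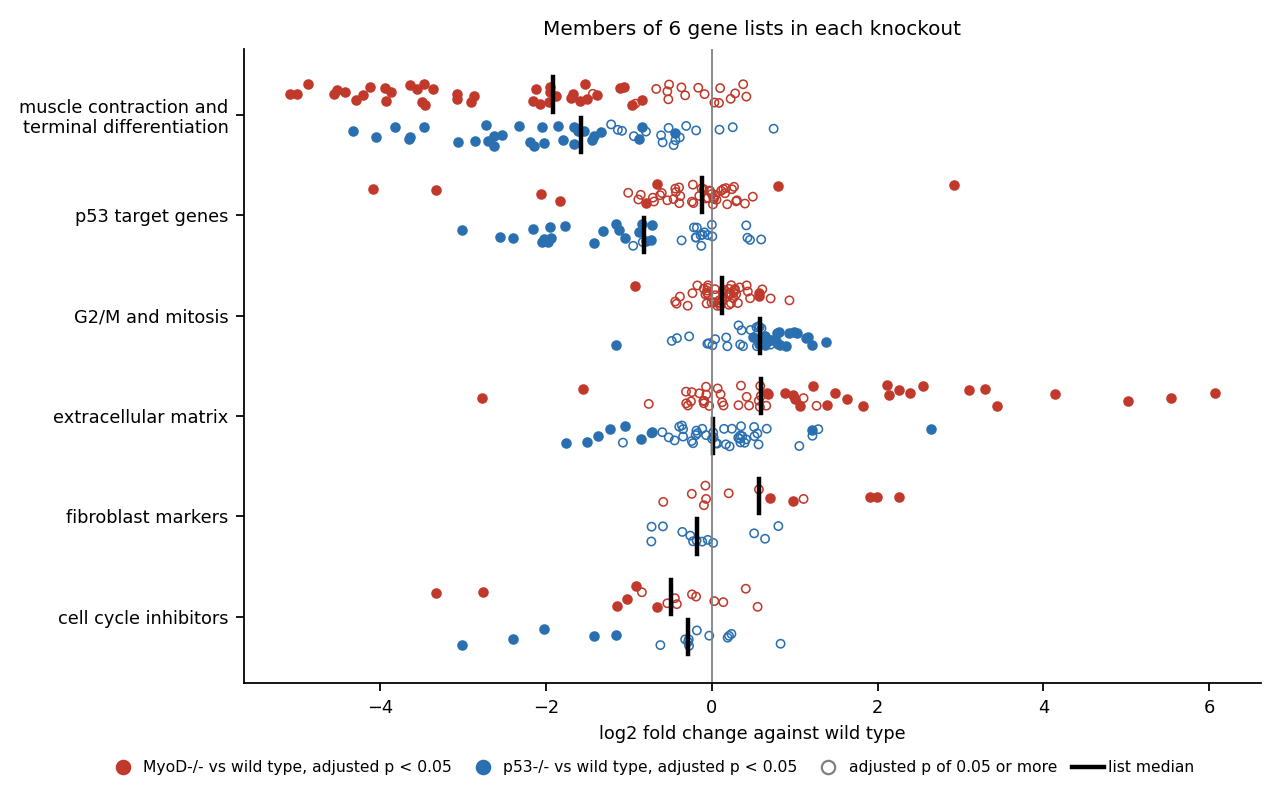
Log2 fold change against wild type of the tested members of 6 gene lists, with 1 point per gene, MyoD-/- in red, p53-/- in blue, filled points for an adjusted p under 0.05 and a black bar at the list median. The medians of the muscle contraction list are -1.92 in MyoD-/- and -1.58 in p53-/-, and those of the extracellular matrix list 0.59 and 0.02.

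p53-/- against wild type asked what the loss of p53 changes in the same cells. Cells without p53 had less RNA for 20 of 38 genes that p53 switches on, such as Cdkn1a, an inhibitor of cyclin-dependent kinases, Mdm2, the ligase that degrades p53, and the cyclin Ccng1. They had more RNA for 19 of 43 genes of G2 and mitosis, among them Birc5 (survivin) and Ect2, an exchange factor of cytokinesis. RNA was lower for 30 of 46 contractile and differentiation genes, and 0 list calls of this comparison held with an estimated correlation between genes. Lower too was RNA for the basement membrane collagens Col4a1 and Col4a2.

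The p53 target genes fell as a group. Of 38 tested genes 0 rose and 20 fell, or 1 and 21 adjusted over the list alone (median -0.81, adjusted p = 1.1e-17, and adjusted p = 0.224 with an estimated correlation). Ccng1 went from 6495 ± 1320 to 736 ± 54 (SD, n = 3), a log2 fold change of -3.01 ± 0.16 (SE, adjusted p = 1.04e-05). Cdkn1a went from 7159 ± 853 to 1349 ± 480 (SD, n = 3), a log2 fold change of -2.40 ± 0.25 (SE, adjusted p = 0.000791), and Mdm2 from 42620 ± 12460 to 9900 ± 849 (SD, n = 3), a log2 fold change of -2.05 ± 0.24 (SE, adjusted p = 0.00109). The adenylate kinase Ak1 changed by log2 -2.56, Gadd45a by -2.03, the RNA-binding protein Zmat3 by -1.95 (not called at another probe set, log2 -0.30, adjusted p = 0.636) and the antiproliferative gene Btg2 by -1.42. Of 16 cell cycle inhibitors 0 rose and 5 fell, or 1 and 5 adjusted over the list alone (median -0.28, adjusted p = 3.55e-05, and adjusted p = 0.36 with an estimated correlation).

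The lists of mitosis and of DNA replication genes were called higher, though most members of each were not called. Of 43 G2/M and mitosis genes 19 rose and 1 fell, or 28 and 3 adjusted over the list alone (median 0.58, adjusted p = 2.88e-10, and adjusted p = 0.378 with an estimated correlation). Ect2 rose by 0.99 ± 0.15 (SE, adjusted p = 0.00274), Birc5 by 1.21 ± 0.21 (SE, adjusted p = 0.00623) and the cyclin Ccnb2 by 0.69 on the log2 scale, while Wee1, a kinase that holds back mitosis and lies on chromosome 7, fell by 1.16. Of 50 G1/S and DNA replication genes 7 rose and 3 fell, or 16 and 3 adjusted over the list alone (median 0.27, adjusted p = 0.00375, adjusted p = 0.622 with an estimated correlation, and adjusted p = 0.177 with fry). The origin recognition gene Orc6 rose by 0.79 (adjusted p = 0.005), and the cyclin Ccnd2 fell by 1.21 (adjusted p = 0.00369). Myc, a growth-promoting transcription factor, rose by 1.22 on the log2 scale (adjusted p = 0.00331).

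Muscle contraction and terminal differentiation genes fell in p53-/- as well, with a median log2 fold change of -1.58. Of 46 tested genes 0 rose and 30 fell, or 37 fell adjusted over the list alone (adjusted p = 5.37e-25, and adjusted p = 0.224 with an estimated correlation). Acta1 changed by log2 -3.82 ± 0.54 (SE, adjusted p = 0.00221), Myh3 by -4.33 ± 0.47 (SE, adjusted p = 0.0008), the troponin Tnnt3 by -4.05 ± 0.54 (SE, adjusted p = 0.00178) and the glycogen phosphorylase Pygm by -3.65 ± 0.41 (SE, adjusted p = 0.000941). Of 26 myogenic regulators 1 rose and 4 fell, or 2 and 6 adjusted over the list alone (median -0.24, adjusted p = 0.0315, and adjusted p = 0.224 with an estimated correlation). That call was lost without wild type A (0.304), B (0.193) or C (0.163), with a stricter filter (0.114) and without the genes of chromosomes 4, 7 and 14 (0.246). Mef2a, a muscle transcription factor on chromosome 7 as is Myod1, changed by log2 -1.60 (adjusted p = 0.00107). The growth inhibitor Mstn changed by -1.81 (adjusted p = 0.00481). Of 17 satellite cell markers 1 rose and 5 fell, or 3 and 8 adjusted over the list alone, and the list was not called (median -0.59, adjusted p = 0.0739). It was called with quantile normalization (0.0459), with median centring (0.0441) or without MyoD-/- B (0.0417). Against no change, fry gave adjusted p = 0.0369 for these markers. Cdh15 changed by log2 -1.23 (adjusted p = 0.00359) and Cxcr4 by -1.37 (adjusted p = 0.00451). Of the 22 Notch pathway genes 0 rose and 2 fell in both counts (adjusted p = 0.158), and Hes6 changed by -1.10 (adjusted p = 0.00276).

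Among the named genes the lowest log2 fold changes belonged to Ly6e, a membrane protein induced by interferon, at -5.05 ± 0.33 (SE, adjusted p = 3.41e-05), to Hoatz, a gene of motile cilia, at -4.79 ± 0.24 (SE, adjusted p = 7.36e-06), and to Ano3, a membrane protein of the anoctamin family, at -4.72 ± 0.21 (SE, adjusted p = 4.86e-06). Igf2, a growth factor on chromosome 7, changed by -3.48 ± 0.48 (SE, adjusted p = 0.00208) and the prostaglandin receptor Ptger4 by -3.72 ± 0.58 (SE, adjusted p = 0.00348). Grem1 rose by 3.82 ± 0.39 (SE, adjusted p = 0.000653), Apbb1ip, an adaptor of Rap1 signalling, by 3.38 ± 0.32 (SE, adjusted p = 0.000471), Igfbp6 by 3.09 ± 0.57 (SE, adjusted p = 0.00743) and Bgn by 2.64 ± 0.52 (SE, adjusted p = 0.0108, not called at another probe set, log2 0.82, adjusted p = 0.113). Among 50 extracellular matrix genes 2 rose and 7 fell, or 6 and 8 adjusted over the list alone, and the list was not called (adjusted p = 0.795). The basement membrane collagens Col4a1 and Col4a2 fell by 1.76 and 1.51 and the laminin Lama2 by 1.37 on the log2 scale. Of 48 growth factors and receptors 2 rose and 8 fell, or 3 and 11 adjusted over the list alone (median -0.23, adjusted p = 0.0471, and adjusted p = 0.556 with an estimated correlation). The call was found in 12 of 26 alternatives (0.0191 to 0.556). It was lost without wild type A (0.0621) or C (0.103), MyoD-/- A (0.0771), and p53-/- A (0.0574) or C (0.221).

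Smooth muscle markers fell, with 0 of 11 genes up and 3 down, the same as adjusted over the list alone (median -0.40, adjusted p = 0.0285, and adjusted p = 0.311 with an estimated correlation). Their call was lost without wild type A (0.058) or p53-/- C (0.108) and with a stricter filter (0.0638). Their member Acta2, the smooth muscle actin, changed by -2.04 (adjusted p = 0.0131, range over 22 alternatives 0.00306 to 0.0516). This call was lost without p53-/- C (0.0516), and its other probe set was not called (log2 -0.10, adjusted p = 0.933). Cholesterol biosynthesis rose, with 3 of 18 genes up and 0 down, or 4 and 0 adjusted over the list alone (median 0.35, adjusted p = 0.0129, and adjusted p = 0.378 with an estimated correlation). It was lost without p53-/- B (0.0646). Idi1, an isomerase of that pathway, rose by 1.09 (adjusted p = 0.00357). The lists of pro-apoptotic genes (2 of 24 up, 2 down, adjusted p = 0.935), anti-apoptotic genes (4 of 21 up, 3 down, adjusted p = 0.795), interferon and antigen presentation (0 of 25 up, 5 down, adjusted p = 0.385), oxidative stress and xenobiotic defence (7 of 36 up, 2 down, adjusted p = 0.41) and immediate-early and stress response (2 of 26 up, 2 down, adjusted p = 0.463) were not called. Adjusted over the list alone, the genes up and down were 2 and 2, 7 and 4, 1 and 6, 9 and 5, and 2 and 5 in these lists, in the same order. Fibroblast markers were not called (0 of 13 changed, adjusted p = 0.795), and 0 of 4 endothelial, 0 of 11 macrophage, 1 of 3 adipocyte and 0 of 10 Schwann and neural markers changed, in both counts, in lists that were not called (adjusted p 0.795 to 0.83). The median, mean and test did not share a sign in the uncalled lists of extracellular matrix, oxidative stress and adipocyte genes.

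In all, 1598 of 15769 probe sets differed between p53-/- and wild type, or 10.1%, with 755 higher and 843 lower. Of these 247 were at least 2-fold higher and 485 at least 2-fold lower. Counted as genes, 1134 of 9013 changed, with 546 up and 588 down, and the arrays did not overlap for 3114 genes, or 34.6%, where chance gives 10%. The count of probe sets was 869 without wild type A, 951 without wild type B, 916 without p53-/- A and 1008 without p53-/- C. It was 1870 with the scan day as a block and 1882 without MyoD-/- A, the only array that this block sets apart here. The block therefore adjusted nothing between p53-/- and wild type. Median centring moved the median of all probe sets by 0.111 on the log2 scale in this comparison and turned the split into 1096 higher and 642 lower.

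On U74Bv2 the lone p53-/- array was compared with the 3 wild-type arrays, with its spread taken from the other groups, so variation between p53-/- samples does not enter its errors and p-values. Of 7866 probe sets 289 differed, with 59 higher and 230 lower. No wild-type array was scanned on the day of this array, and with the scan day as a block 9 probe sets were called, 5 of them among the 289, while all 289 kept their sign. Trp53inp1, a p53 target gene, was at 6001 ± 909 (SD, n = 3) in wild type and 169 in this array, a log2 fold change of -4.28 ± 0.38 (SE, adjusted p = 0.00389). Pmaip1, another target, changed by log2 -2.93 ± 0.26 (SE, adjusted p = 0.00389), and Cpt1c, a carnitine palmitoyltransferase, by -3.94 ± 0.25 (SE, adjusted p = 0.000631). Ddit4l, an inhibitor of mTOR signalling, changed by log2 -3.92 and the muscle genes Smpx, Stac3 and Klhl41 by -3.35, -2.95 and -2.86. Nfib, a transcription factor, rose by 3.21 ± 0.43 (SE, adjusted p = 0.00894). With the scan day as a block Trp53inp1 (-3.30, adjusted p = 0.0442), Cpt1c (-3.64, adjusted p = 0.0371) and Nfib (4.33, adjusted p = 0.0371) were called at these probe sets. Another probe set of Trp53inp1 (-1.29, adjusted p = 0.279) and 1 of 2 others of Nfib (2.07, adjusted p = 0.122) lost their calls. Lost too were Pmaip1 (-2.41, adjusted p = 0.0616), Ddit4l (-3.13, adjusted p = 0.089), Smpx (-3.19, adjusted p = 0.125), Stac3 (-3.52, adjusted p = 0.0588) and Klhl41 (-2.62, adjusted p = 0.2).

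The comparisons shared genes: 549 of 15769 probe sets on U74Av2 and U74Cv2 were called in both knockouts. Muscle genes such as Acta1, Myh3 and Car3 fell in both, and Myf5, Grem1 and Bgn rose in both. Of the 549 probe sets 505 changed in the same direction, 185 up and 320 down, where independent lists would share 36.0 and 45.1, numbers that do not allow for the wild-type arrays common to both comparisons. The log2 fold changes correlated across probe sets with r = 0.494 (probe sets are not independent replicates), and r was 0.497 in 100 simulations with no changes in the knockouts, because both comparisons use the same wild-type arrays. The covariance was 0.191 against 0.0546 in the simulations. The count of 505 fell to 280 without wild type A, 251 without wild type B and 327 without p53-/- A. Genes of chromosome 14 shifted up and those of chromosome 7 down in both knockouts, as described below. Without the genes of chromosomes 4, 7 and 14 the count was 360, where fewer probe sets were tested. On U74Cv2 no knockout array with a recorded chip lot shared the lot of wild type. A lot effect there would show as changes shared by both knockouts and cannot be told apart from them.

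Probe sets called in both knockouts with opposite signs numbered 44, of which 28 were higher in MyoD-/- and lower in p53-/- and 16 the reverse, where independent lists would share 40.1 and 40.4. Among the 41 with a gene name, chosen after their values were seen, were Ifi47, a GTPase induced by interferon (log2 3.62 in MyoD-/- and -1.46 in p53-/-), Sparc, a matrix glycoprotein (1.38 and -0.72), Cdh11, a cadherin of mesenchyme (1.61 and -1.35), Ctsh, a lysosomal protease (1.63 and -1.16), Igf2r, the receptor that clears Igf2 (0.94 and -0.83), and the transcription factor Six2 (-2.01 and 1.74). The count was 14 without wild type A, 20 without wild type B, 19 without wild type C, 24 without MyoD-/- B, 17 without p53-/- A and 27 without p53-/- C, and 29 with median centring and 29 with no filter.

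**Figure D3:**
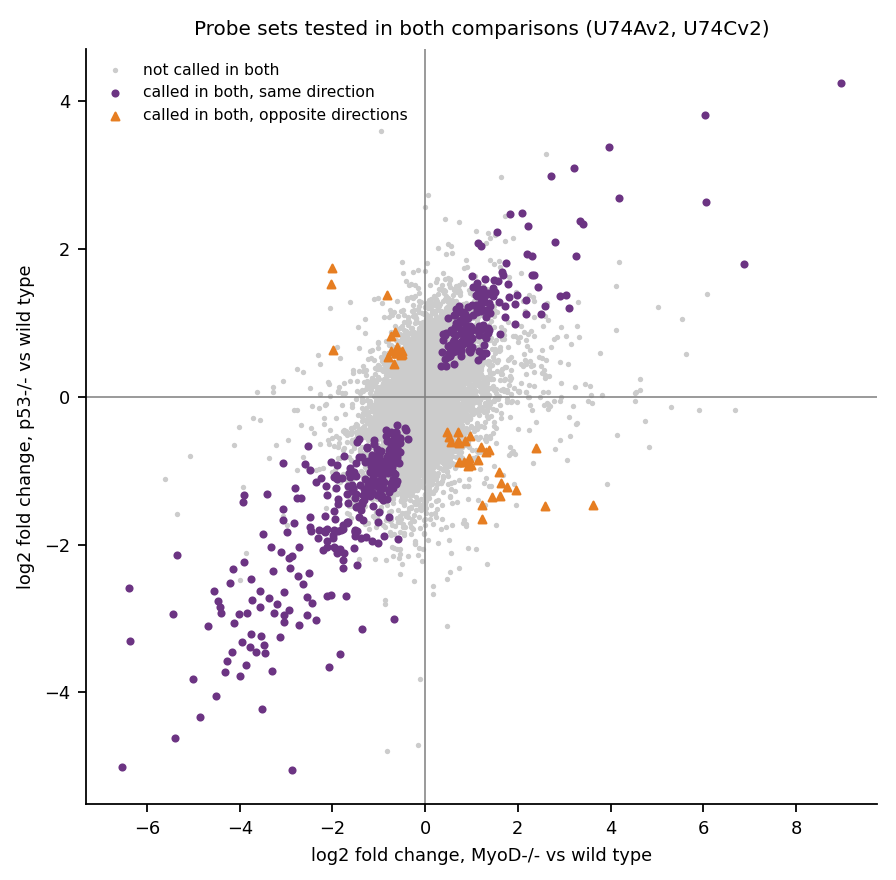
Log2 fold change in MyoD-/- (x axis) against that in p53-/- (y axis), both against wild type, with 1 point per probe set tested on U74Av2 and U74Cv2. Purple points, 505 in number, were called in both in the same direction, orange triangles, 44 in number, were called in both in opposite directions, and gray points were not called in both.

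MyoD-/- against p53-/- asked directly where the knockouts differ. More RNA was found in MyoD-/- for 23 of 50 matrix genes, 13 of 48 growth factors and receptors, and 17 of 38 p53 target genes, such as Ccng1, Cdkn1a and Mdm2. The same held for 7 of 25 genes of the interferon response, such as the GTPase Irgm1. Less RNA was found for 11 of 50 genes of DNA replication and 14 of 43 of mitosis, and for the acetylcholine receptor subunit Chrna1 and the cadherin Cdh15. With an estimated correlation between genes 0 of the list calls held.

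Extracellular matrix genes were higher in MyoD-/- in 23 of 50 tested genes and lower in 1, or 26 and 1 adjusted over the list alone (median 0.77, adjusted p = 1.8e-13, and adjusted p = 0.0599 with an estimated correlation). Sparc was higher by 2.11 ± 0.18 (SE, adjusted p = 7.14e-05), the protease Mmp3 by 4.66 ± 0.42 (SE, adjusted p = 0.000106) and Lox by 4.48 ± 0.51 (SE, adjusted p = 0.000468) on the log2 scale. Growth factors and receptors were higher in 13 of 48 genes and lower in 4, or 15 and 5 adjusted over the list alone (median 0.38, adjusted p = 5.6e-05, and adjusted p = 0.533 with an estimated correlation). Ccn2 stood at 4.70 ± 0.45 (SE, adjusted p = 0.000168) and Fgf7, a growth factor of epithelia, at 3.32 (adjusted p = 0.000418). Fibroblast markers were higher in 4 of 13 genes and lower in 0, or 5 and 0 adjusted over the list alone (median 0.56, adjusted p = 0.000785, and adjusted p = 0.564 with an estimated correlation). The transcription factor Prrx1 stood at 1.20 (adjusted p = 0.00231). The p53 target genes were higher in 17 of 38 and lower in 2, or 19 and 4 adjusted over the list alone (median 0.49, adjusted p = 5.33e-08, and adjusted p = 0.533 with an estimated correlation). Among them were Ak1 at 2.73, Ccng1 at 2.35, Mdm2 at 2.01 and Cdkn1a at 1.86. Interferon and antigen presentation genes were higher in 7 of 25 and lower in 0, the same as adjusted over the list alone (median 0.19, adjusted p = 0.011, and adjusted p = 0.564 with an estimated correlation). Without MyoD-/- A the call was lost (0.0958), and Irgm1 stood at 2.99 (adjusted p = 0.000156).

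Lower in MyoD-/- were 11 of 50 G1/S and DNA replication genes against 2 higher, or 16 and 3 adjusted over the list alone (median -0.38, adjusted p = 0.000796, adjusted p = 0.564 with an estimated correlation, and adjusted p = 0.0722 with fry). Of 43 G2/M and mitosis genes 14 were lower and 1 higher, or 18 and 1 adjusted over the list alone (median -0.50, adjusted p = 5.74e-05, and adjusted p = 0.564 with an estimated correlation). Members of this list were Ect2 at -0.90 (adjusted p = 0.00314) and Kif2c, a kinesin of the mitotic spindle, at -0.87 (adjusted p = 0.00784). Muscle contraction genes were lower in 10 of 46 and higher in 1, or 14 and 4 adjusted over the list alone (median -0.32, adjusted p = 0.0143, and adjusted p = 0.812 with an estimated correlation). The muscle call was lost without p53-/- B (0.23), without MyoD-/- A (0.0958) and with the scan day as a block (0.0869), which here in effect leaves out MyoD-/- A. Against no change, which is another question, fry gave adjusted p = 0.234. Chrna1 changed by -4.29 ± 0.50 (SE, adjusted p = 0.000528) and Des by -2.51 (adjusted p = 0.000992). Satellite cell markers were lower in 6 of 17 and higher in 2, the same as adjusted over the list alone (median -0.26, adjusted p = 0.0483, under 0.05 in 16 of 26 alternatives, and adjusted p = 0.564 with an estimated correlation). Their call did not hold without wild type B (0.0598), MyoD-/- B (0.0591) or C (0.0634), or p53-/- B (0.107). The 13 other lists were not called. Anti-apoptotic genes (adjusted p = 0.0572) were called without wild type C (0.0256), MyoD-/- A (0.0327) or p53-/- C (0.0155), and smooth muscle markers (adjusted p = 0.123) without wild type C (0.045) or MyoD-/- A (0.0327). Against no change, fry gave adjusted p = 0.00613 for anti-apoptotic genes, 0.033 for smooth muscle markers and 0.0494 for myogenic regulators. Schwann and neural markers (adjusted p = 0.803) were called without MyoD-/- A (0.0327) and oxidative stress genes (adjusted p = 0.374) without p53-/- B (0.0496). Among them the median, mean and test did not share a sign for myogenic regulators, Notch pathway and cell cycle inhibitors.

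Among the named genes the highest log2 fold changes between the knockouts belonged to Serpinb9b at 6.87 ± 1.18 (SE, adjusted p = 0.00407), Ephx1 at 5.11 ± 0.35 (SE, adjusted p = 1.94e-05) and Ifi47 at 5.08 ± 0.39 (SE, adjusted p = 3.88e-05). Ano3 stood at 4.56 ± 0.21 (SE, adjusted p = 2.34e-06). Lower in MyoD-/- were Six2 at -3.75 ± 0.29 (SE, adjusted p = 4.12e-05), Egln3, a prolyl hydroxylase that marks hypoxia-inducible factor, at -3.61 ± 0.23 (SE, adjusted p = 1.26e-05) and the homeobox gene Pitx3 at -3.25 (adjusted p = 0.00121). In all, 2045 of 15769 probe sets differed, or 13%, with 977 higher and 1068 lower, of which 552 and 338 by at least 2-fold. Counted as genes, 1451 of 9013 differed, and the arrays did not overlap for 3116 genes, or 34.6%, where chance gives 10%. The count was 1266 without MyoD-/- B, 1348 without p53-/- A and 1340 without p53-/- C.

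Genes of chromosomes 7, 4 and 14 shifted as groups, which was seen and analysed after the other results. Many of the genes that fell in p53-/- lie on chromosome 7, such as the muscle genes Ryr1, Tnnt3 and Atp2a1, the growth factor Igf2 and the chaperones Bag3 and Serpinh1. Only genes with a mean percentile of signal above 50 were used for this. The 559 such genes of chromosome 7 had a median shift of -0.397 on the log2 scale in p53-/- relative to all genes, and 0 of 10000 random sets of as many genes with like signal lay as low. Of them 5 rose and 156 fell, or 28.8% called against 14% of all these genes. Igf2 (log2 -3.48) fell by far more than the median of the group, while Myod1, on the same chromosome, fell by 0.89. How much of either fall goes with the shift of the group was not tested. The median absolute shift of the 20 chromosomes was 0.0427. The shift was -0.382 with quantile normalization and -0.398 with median centring. In MyoD-/- the 621 genes of chromosome 4 shifted by -0.236, with 15 up and 108 down, and the 735 genes of chromosome 7 by -0.147, with 23 up and 93 down. On U74Cv2 alone these chromosome 7 shifts were smaller. The MyoD-/- arrays averaged -0.0277 ± 0.0204 there (SE, n = 3), against -0.184 ± 0.0203 on U74Av2 and -0.186 ± 0.0228 on U74Bv2. The p53-/- arrays stood at -0.219, -0.154 and -0.143 on U74Cv2 and at -0.591, -0.486 and -0.572 on U74Av2. Chromosome 14 genes were higher than in wild type in both knockouts, by 0.329 in MyoD-/- and 0.27 in p53-/-, and the wild-type samples themselves stood apart there, with C at 0.216, A at -0.0768 and B at -0.151.

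**Figure D4:**
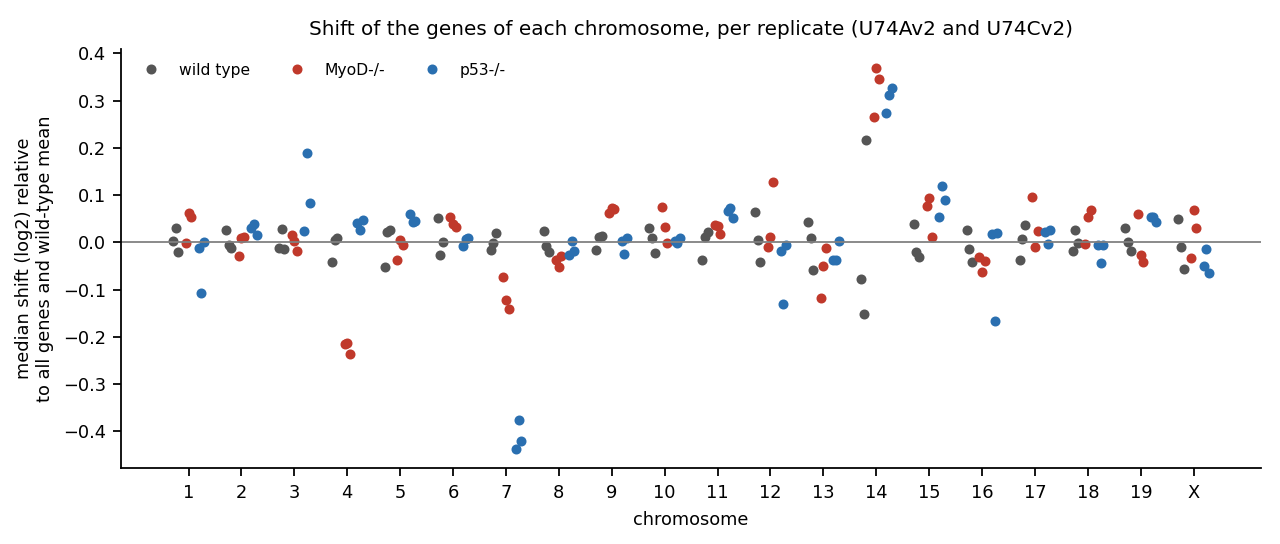
Median shift on the log2 scale (y axis) of the genes of each chromosome (x axis) relative to all genes and to the wild-type mean, with 1 point per sample over U74Av2 and U74Cv2, and 3 samples per genotype. Chromosome 7 lies at -0.438, -0.375 and -0.42 in p53-/-, chromosome 4 at -0.216, -0.213 and -0.236 in MyoD-/-, and chromosome 14 at 0.216 in wild type C.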

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

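The tests of the share of muscle cells and of fibroblasts in place of muscle cells, of chromosome 4, of chromosome 7 in MyoD-/-, of parts of chromosome 7 and of scan days for both chromosomes were chosen after the results were seen, and the rule for the share of muscle cells in p53-/- was revised 2 times after that. A set of 44 probe sets drew attention because the knockouts moved them in opposite directions against wild type, and the call of their direct contrast, which sums the changes, follows from that and is no further evidence. Without wild type A the count was 14, and leaving out wild type B or C, MyoD-/- B, or p53-/- A or C gave 20, 19, 24, 17 and 27, and it was 29 with median centring and 29 with no filter. The shift of chromosome 7 genes by -0.544 on the log2 scale in the lone p53-/- array on U74Bv2 drew attention because the comparison of p53-/- with wild type on the other chip types does not use that array. No wild-type array shared its scan day, on which MyoD-/- B and C lay at -0.199 and -0.218. For each comparison the 6 samples can be split in 10 ways, too few for a share under 0.05, and the 1 real split gave 2515 calls in MyoD-/- against 0 in the highest of the others. The values were 1598 against 4 in p53-/- and 2045 against 0 between the knockouts. Each of the other splits mixed the genotypes within its groups, which widens the spread there by construction. Their low counts therefore measure no chance level, and nothing is concluded from them.

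Muscle contraction genes fell in both knockouts, by medians of 1.92 and 1.58 on the log2 scale, and scaling of the arrays as the whole cause is argued against, since the median nearest to 0 under quantile normalization or median centring was -1.46. In p53-/- a smaller share of muscle cells would raise the markers of every other cell type alike. Under the rule set for it the smooth muscle markers alone went against this. Over the 8 genes that no other list holds they had a mean of -0.88 ± 0.285 (SE over genes), more than 2 SE below 4 of the other 5 lists. Without 1 sample or under both scalings the mean was -0.999 to -0.715, below 2 to 4 lists. Whether muscle cells express these genes was not tested, and if they do, the markers would fall with them, so a smaller share stays open. With the smooth muscle list set aside nothing is decided. The call of that list was lost without wild type A (0.058) or p53-/- C (0.108) and with an estimated correlation (0.311). The fibroblast markers, at -0.0966 ± 0.136 (SE over 13 genes), argue against fibroblasts in place of muscle cells in p53-/-. In MyoD-/- a smaller share of muscle cells stays open, because the lowest list, the endothelial markers, lay at -0.0556 ± 0.292 (SE over 5 genes). Fibroblasts in place of muscle cells remain a candidate explanation there, with a mean of 0.666 ± 0.258 for their markers (SE over 13 genes, not over samples). Some values go the other way. Col3a1 (log2 -0.24) and Pdgfra (log2 -0.08) were not called, and Myf5, a purity marker of the myoblasts in the labels, rose from 726 to 4331. A lower readiness to differentiate in both knockouts is a biological explanation that was not tested apart from these.

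Extracellular matrix genes rose in MyoD-/-, by a median of 0.59 on the log2 scale. Scan day and scaling are argued against as the whole cause, since the median was 0.573 with the scan day as a block and at least 0.611 under both scalings. Fibroblasts in the MyoD-/- cultures may have added to it, since the 8 fibroblast markers outside the matrix list had a median log2 fold change of 0.633 and 6 of them were higher. Col1a1 rose from 994 to 4950 and S100a4 from 23750 to 45360, but Col3a1, at 8602 in wild type and 7227 in MyoD-/-, did not rise, and the purity above 98% in the labels rests on desmin, Myf5 and MyoD, of which Des and Myod1 fell in MyoD-/- and Myf5 rose from 726 to 4331, so it cannot be read alike there, and the preplating named in the labels is meant to remove fibroblasts. A change of the myoblasts themselves through the loss of MyoD stays open too and was not tested apart from this.

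Genes of chromosomes 7, 4 and 14 shifted as groups. A change in 1 part of chromosome 7 alone is argued against, because all 10 parts of the chromosome with equal numbers of genes had a median shift below -0.1 in p53-/-, and so are scan days, because on U74Av2, with arrays of a shared day, the shift nearest to 0 was -0.486 for chromosome 7 in p53-/- and -0.227 for chromosome 4 in MyoD-/- B and C. Changed copy number in these passaged cultures is a candidate explanation for chromosome 7 in p53-/-, with -0.544 on U74Bv2, although it does not say why U74Cv2 gave only -0.219 to -0.143, and for chromosome 4 in MyoD-/-, with -0.203 on the chip type where it lay nearest to 0. For chromosome 7 in MyoD-/- it stays undecided, since the mean shift on U74Cv2 was -0.0277 ± 0.0204 (SE, n = 3). Copy number of chromosome 14 in wild type A and B could likewise give the difference of 0.516 between wild type C and their mean on U74Bv2, although it was 0.183 on U74Cv2, and genotype cannot be the cause of a difference within wild type, but the values on U74Bv2 repeat the shifts in the same RNA with other probes and favour copy number no more than other causes, no DNA was measured, and the mouse strains, and for chromosomes 7 and 4 the genotypes, stay open as other causes.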

How the results depend on the processing

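The fits without the genes of chromosomes 4, 7 and 14 and the scan day block of the lone p53-/- array were added after the data had been seen, and the other alternatives were planned. Over 24 alternatives the count of changed probe sets in MyoD-/- was 1452 to 2701, in p53-/- 869 to 1917 and, over 23, between the knockouts 1266 to 2118, and the overlap in the same direction was 251 to 569 and that in opposite directions 14 to 53. The values 2701, 2118 and 569 came with the chip lot on U74Cv2 as a random block. That block cannot separate lot from genotype, because no knockout array with a recorded lot shared the lot of wild type there. Leaving out 1 sample at a time gave 1452 to 2506 in MyoD-/-, 869 to 1882 in p53-/-, 1266 to 1945 between the knockouts and 251 to 477 for the overlap, where fewer arrays widen the errors by construction, and why some samples counted for more was not tested. On U74Av2 and U74Cv2 alone MyoD-/- gave 1561, where fewer probe sets were tested. With an estimated correlation between genes the lists called were 1 in MyoD-/-, 0 in p53-/- and 0 between the knockouts, against 10, 9 and 9. In MyoD-/- the estimate was 0.202 for muscle contraction genes. It lay below the preset 0.01 for myogenic regulators (-0.0324) and fibroblast markers (-0.0571), so it does not explain their lost calls. This alternative also used camera on the arrays in place of cameraPR on the t values. Its p-values then rest by construction on the few degrees of freedom between arrays. A call lost there is therefore no measure of correlation between genes alone, and the part of each was not tested. In the other alternatives the lists called were 8 to 12 in MyoD-/-, 6 to 10 in p53-/- and 8 to 11 between the knockouts. The 289 probe sets of the lone p53-/- array were 341 with quantile normalization, 196 with no filter, 283 with no offset and 9 with the scan day as a block, which leaves fewer degrees of freedom by construction.

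With the replicate letter as a block the counts were 2167, 1395 and 1800. Same-letter deviations of different genotypes correlated at -0.12 to 0.128 and those of different letters at -0.124 to 0.111, so the letters do not pair the samples. With the scan day as a block the counts were 1847, 1870 and 1772, and without MyoD-/- A they were 2168, 1882 and 1733. On U74Av2 and U74Cv2 the block sets that array alone apart. For p53-/- and for the contrast of the knockouts it is therefore no check apart from leaving out MyoD-/- A. Without the genes of chromosomes 4, 7 and 14 they were 1992, 1149 and 1621, and the overlap was 360. Median centring turned the p53-/- split to 1096 higher and 642 lower and the split between the knockouts to 771 and 1286.

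Called named genes kept their direction under every alternative of offset, scaling, filter, fit, block and samples in which they were tested. The 283 results of named genes were counted per gene and comparison, with genes not called in the main fit included. Of these, 265 were tested with the stricter filter, 267 without MyoD-/- A, B or C, and 277 without wild type A, B or C. Rasgrf1 and Serpinb9b in MyoD-/-, for example, were tested in 19 of 22 alternatives. The most calls were lost without MyoD-/- B, 21 among 267 results tested. With double the offset 0 calls were lost among 283 results tested. Taking another probe set of the same gene left the call as it was in 58 of 102 cases, lost it in 30, gained it in 3 and reversed the sign in 11, none of these past the threshold, and the cause was not tested. In MyoD-/- the reversed log2 values were 0.023 for E2f3, -0.27 and -0.22 for Cflar and 0.0194 for Akt2. In p53-/- they were -0.46 for Pmvk, 0.0807 for Akt2, 0.0721 for Gpx3, -0.28 for Ier3 and -0.0373 for Prdx4. Between the knockouts they were 0.11 for Pmvk and -0.14 for Gpx3. Probe sets with signals near the background, above the 40th percentile in fewer than 3 arrays, were not tested, so genes of low signal such as Pax3 cannot be judged, and the offset understates changes of dim genes.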

Other observations

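The test of imprinted genes was chosen after the results were seen. Some paternally expressed genes fell in both knockouts. Mest changed by log2 -6.36 in MyoD-/- and -3.31 in p53-/-, Peg3 by -5.35 and -2.14, and Plagl1, a zinc finger gene, by -3.29 and -2.36. Igf2 changed by -1.84 and -3.48. Of genes expressed from the maternal copy, Gatm, an enzyme of creatine synthesis, changed by -3.90 and -1.33, and Igf2r rose by 0.94 in MyoD-/- and changed by -0.83 in p53-/-, while the paternally expressed Rasgrf1 rose by 4.65 in MyoD-/-. Of 36 imprinted genes 12 were called in MyoD-/-, 6 higher and 6 lower, or 33.3% against 12.9% of the other genes (Fisher's exact test, two-sided, p = 0.00136). In p53-/-, outside chromosome 7, 5 of 18 were called, 1 higher and 4 lower, or 27.8% against 11.5% (Fisher's exact test, two-sided, p = 0.0481). The list was made after Mest and Peg3 had been seen among the largest changes, so these tests are not independent of them, and more frequent change of imprinted genes, with no shared direction in MyoD-/-, is a hypothesis only.

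Sex-linked genes differed between the samples of a genotype. Xist, which is transcribed from the inactive X chromosome, had signals of 111.1, 6495 and 39.8 in wild type A, B and C, of 2894, 3859 and 4514 in MyoD-/-, and of 4428, 25.7 and 21.1 in p53-/-. Eif2s3y, a gene of the Y chromosome, had signals of 813, 16.9 and 1280 in wild type, of 8.11, 37.4 and 81.5 in MyoD-/-, and of 24.1, 582 and 5.64 in p53-/-. Xist was high in every MyoD-/- sample but only in wild type B and p53-/- A, so the genotypes were not balanced in it. Both genes were low in p53-/- C. Neither was called in MyoD-/- against wild type (adjusted p = 0.327 and 0.246), but with so wide a spread within wild type this is no evidence of balance. The sex of the mice is not given in the sources used here.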
